A study of Mus musculus with 4 samples.

How the data were processed

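RNA of tumour-associated macrophages was sequenced in 4 libraries, 2 from mice fed a high-fat diet and 2 from mice fed a control diet. Per the labels' protocols, the cells were sorted from tumours of the MC38 model as positive for CD45, CD11b and F4/80, total RNA was extracted with a column kit, and polyA RNA was made into libraries with a stranded mRNA kit. MC38 is a mouse colon carcinoma line that is grafted into C57BL/6 mice. Each title names a mouse, so the 2 libraries of a diet were treated as 2 animals.

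The deposited table held counts, whole numbers of reads per gene and library that the authors had not normalised, for 53379 versioned Ensembl mouse gene identifiers. Per the submitters' processing notes, cutadapt 1.15, FastQC 0.11.5, BWA 0.7.12 and DESeq2 1.24.0 were used, and the genome builds named are GRCm38 and mm10. The role of each tool, the counting program, its strand setting, its treatment of reads that match several places and the gene annotation release are not given in the sources used here. Every column of values belonged to one of the 4 libraries. Total counts were 36898146 and 37147582 in the high-fat-diet libraries and 34148682 and 37159552 in the control-diet libraries.

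Symbols were matched by identifier for 53274 of the identifiers, and the other 105 held between 0.012 and 0.0129% of each library's counts. Where a symbol belonged to several identifiers, it was kept for the identifier with the most counts. Positions, exon structure, transcript length and GC content came from GENCODE mouse release 21 on GRCm38. The version of the identifier was the same there for 50604 identifiers (94.8%), and coordinates are given only for those. Reads shared between a gene and a near-identical copy could have been split in the counting: processed pseudogenes took 6.51 to 7.37% of the counts per library.

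Genes were tested with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr at its defaults, a minimum count of 10 and a minimum total of 15, left 18422 genes. Libraries were scaled by TMM, dispersions were estimated robustly, and the quasi-likelihood test (glmQLFit, glmQLFTest) compared high-fat diet minus control diet with the diet as the only term. P-values were adjusted by the Benjamini-Hochberg method, and a gene is called higher or lower here at an adjusted p below 0.05. Values are CPM, counts relative to the TMM-scaled size of the library, as mean ± SD over 2 mice, and the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Where all libraries of a diet held 0 counts of a gene, the fold is given as a lower bound against 3 counts over the diet, and where they held 1 to 3 counts together the ratio is given with an exact conditional 95% interval. Such bounds and intervals sum the counts of a diet's 2 mice, so they cover counting error only and not the spread between mice. Nor do the reads carry molecular identifiers that would tell copies of 1 molecule apart.

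Before the data were examined, 38 gene lists were fixed: lists of macrophage biology, lists that follow RNA quality and cell handling, and markers of cell types that the sort could have let through. A list with at least 5 tested members was tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 37 lists tested. Camera with a correlation estimated from the residuals, and fry, were run beside it. With 2 residual degrees of freedom, camera with an estimated correlation can hardly reach a small p. Fry's directional p tests whether a list's genes move on balance 1 way, and its mixed p whether they change in either direction.

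The genes named in the text were chosen by a rule fixed before the data were examined. It takes the sort markers Ptprc, Itgam and Adgre1. It takes, in each direction, the 10 called genes with the largest log2 fold change among those with an average log2 CPM of at least 3 whose 2 libraries of a diet lay on the same side of both libraries of the other diet, passing over predicted genes, pseudogenes and variable segments of immunoglobulins and T cell receptors. It takes up to 4 members of smallest p from each described list, and 10 genes often measured in macrophages of obese hosts or tumours. Genes named outside this rule are said to be chosen after their values were seen.

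Low-count genes, with an average log2 CPM below 2, were placed by their distance to the nearest expressed gene, one with an average log2 CPM of at least 5, as downstream of its 3' end or upstream of its 5' start. Medians of such classes have bootstrap 95% intervals over genes, which are not independent replicates. The correction for GC content and transcript length fitted, for each library, splines with 5 degrees of freedom each to the deviation of log2 CPM from the mean over libraries. The splines were fitted on genes with an average log2 CPM of at least 3 and then applied to genes of lower counts too.

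The steps were tested on simulated counts drawn from the real means and library sizes for the comparison of 2 against 2 libraries, with 17955 genes tested. Changes were planted only in genes with an average log2 CPM of at least 1. Noise was independent between genes and of the same spread in both diets, without shifts by GC content or gene position. The rates therefore do not carry over to lower counts, to such shifts or to diets of unequal spread. Of 100 genes changed by a log2 fold of 1, 52 were recovered with the right sign, of 100 changed by a log2 fold of 2, 97 were, and of 17755 unchanged genes 17 were called. The alternatives tried were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of at least 1 CPM in 2 libraries, a fit without robust estimation, the replicate number as a block, a log2 fold change of at least 1, an adjusted p below 0.10, and leaving out each library in turn. A correction for GC content and transcript length, a fit without genes near gene ends, a fit also without genes that overlap an expressed gene, and a crossed pairing of the mice were added after the data were seen.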

Results

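Macrophages sorted from MC38 tumours 21 days after implantation were compared between mice on a high-fat diet and mice on a control diet, with 2 mice per diet. The comparison asks which transcripts of tumour-associated macrophages differ with the diet of the host. Libraries held 34148682 to 37159552 counts, and 17308 to 18908 genes had at least 10 counts.

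The libraries separated by diet. The correlation of log2 CPM across genes was 0.99 between the high-fat-diet mice and 0.977 between the control-diet mice, against 0.931 to 0.947 between diets. Of 18422 genes tested, 480 were called higher and 1457 lower in the high-fat-diet libraries, and 312 of the former and 1214 of the latter changed at least 1 unit on the log2 scale. In 11759 genes (63.8%) the libraries of the diets did not overlap, where chance gives 33.3% for a single gene with 2 mice against 2. The genes share the same libraries and are not independent, so the excess over 33.3% does not test the diet. The counts of calls fell when either high-fat-diet mouse was left out and rose when either control-diet mouse was. Such a fit takes its spread between mice from the other diet's pair. Over 10214 genes with an average log2 CPM of at least 3, the SD of the log2 difference was 0.276 between the high-fat-diet and 0.402 between the control-diet mice. Without high-fat-diet mouse 1 there were 71 higher and 300 lower genes, and without high-fat-diet mouse 2 there were 117 and 312. Without control-diet mouse 1 there were 855 and 1681, and without control-diet mouse 2 there were 1934 and 2534. Of the 10 leading genes in each direction, 6 were called in each of these 4 fits.

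The markers of the sort did not differ detectably. Ptprc, which encodes CD45, had 456 ± 76.1 CPM in the high-fat-diet and 554 ± 27.5 CPM in the control-diet libraries (SD, n = 2, edgeR adjusted p = 0.323). Itgam, which encodes CD11b, had 420 ± 52.3 and 415 ± 94.6 CPM (adjusted p = 0.96), and Adgre1, which encodes the F4/80 antigen, had 323 ± 27.4 and 302 ± 107 CPM (adjusted p = 0.823). Of the 19 tested members of the macrophage identity list, 0 were called by edgeR, nor was any when adjusted over the list alone. The list's camera adjusted p was 0.433. The smallest p belonged to Aif1, with 358 ± 28.8 against 233 ± 8.14 CPM (adjusted p = 0.0525), and Ms4a7, with 260 ± 4.86 against 108 ± 54.1 CPM (adjusted p = 0.0628).

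Among the genes that rose most in the high-fat-diet libraries, Apoe was by far the most abundant. Apoe, which encodes the lipid carrier apolipoprotein E, lies on chromosome 7 from 19696109 to 19699188 (GRCm38). It had 10054 ± 55.8 CPM in the high-fat-diet and 2455 ± 232 CPM in the control-diet libraries (SD, n = 2), a log2 fold change of 2.03 (SE 0.18, adjusted p = 0.00637). Gpr34, a receptor for lysophosphatidylserine, rose 9.34-fold from 3.26 ± 2.65 to 30.7 ± 12.8 CPM. Fcrls, an Fc receptor-like gene expressed by microglia, rose 4.49-fold from 36.1 ± 4.15 to 162 ± 79.9 CPM. Pf4, a CXC chemokine, rose 3.82-fold to 83.1 ± 22.5 CPM. Klra17, of the lectin-like receptor family Ly49, rose 6.25-fold to 15.5 ± 0.137 CPM, and Ifnlr1, a receptor chain for lambda interferons, rose 7.5-fold to 14.5 ± 6.78 CPM. The other leading genes encode extracellular matrix, and fibroblast and pericyte markers, Col1a2 and Postn among them, were higher as a list (9 of 19 called, median log2 fold change 1.47, camera adjusted p = 2e-07, adjusted p = 0.885 with an estimated correlation). Col1a2 rose 11.1-fold (log2 fold change 3.47, SE 0.43), Col1a1 rose 6.65-fold to 155 ± 81.4 CPM, Postn (chromosome 3, 54361109 to 54391037) rose 8.35-fold to 29.7 ± 2.19 CPM (adjusted p = 0.00416) and Bgn rose 3.89-fold. Calls of Gpr34 (adjusted p = 0.266 and 0.152), Bgn (0.106 and 0.146) and Pf4 (0.217 and 0.224) ended without high-fat-diet mouse 1 and without high-fat-diet mouse 2, and that of Col1a1 without control-diet mouse 2 (0.0606). Leaving out 1 library moved some folds by over 1.5 times, on the log2 scale Fcrls to 1.57, Col1a2 to 2.78 and Col1a1 to 2.08 without high-fat-diet mouse 2, and Gpr34 to 2.58 and Bgn to 2.59 without control-diet mouse 1. Further moves were Gpr34 to 4.46 and Pf4 to 2.67 without control-diet mouse 2.

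Among the genes that fell most, Nr4a3, an orphan nuclear receptor induced early after stimulation, lies on chromosome 4 from 48045153 to 48086447 and fell 33.9-fold from 284 ± 120 to 8.35 ± 0.536 CPM (SD, n = 2, log2 fold change -5.08, SE 0.35, adjusted p = 0.00515). Arc, an activity-induced gene, fell 18.8-fold from 35.7 ± 3.93 to 1.9 ± 0.191 CPM. Adora2a, an adenosine receptor gene, fell 23.1-fold from 21.4 ± 16.6 CPM, and Hdc, the enzyme that makes histamine, fell 17.2-fold from 38.7 ± 28.9 CPM. Gzma, a granzyme of cytotoxic lymphocytes, fell 32-fold from 16.6 ± 15.1 CPM. Ace, the angiotensin-converting enzyme, fell 34.7-fold from 55.5 ± 68.2 CPM (adjusted p = 0.0496), with 104 CPM in control-diet mouse 1 and 7.31 CPM in control-diet mouse 2. Pygm, the muscle glycogen phosphorylase (chromosome 19, 6384399 to 6398459), fell 58.2-fold from 29.4 ± 4.18 to 0.5 ± 0.103 CPM. Iqcn fell 56.2-fold, Ildr1 fell 30.9-fold and Plekhg6 fell 20.8-fold. Of these 10 genes, 4 start within 30 kb past the 3' end of an expressed gene, against 2 of the 10 leading higher genes and 21.2% of all tested genes. Pygm lies 6.37 kb past Sf1, Iqcn 2.84 kb past Jund, Adora2a 4.13 kb past Specc1l and Plekhg6 0.176 kb past Tnfrsf1a, and of the higher genes Apoe lies 2.12 kb past Tomm40 and Ifnlr1 7.69 kb past Gm12989. Calls of Ace (adjusted p = 0.664 and 0.563), Gzma (0.319 and 0.277), Adora2a (0.244 and 0.171) and Hdc (0.319 and 0.225) ended without high-fat-diet mouse 1 and without high-fat-diet mouse 2. Some folds moved by over 1.5 times, on the log2 scale Gzma to -6.11 without high-fat-diet mouse 1, and Gzma to -4.35 without high-fat-diet mouse 2. Likewise, Adora2a moved to -3.38, Hdc to -3.02, Gzma to -3.52 and Ace to -2.19 without control-diet mouse 1, and Adora2a to -5.16, Hdc to -4.72, Gzma to -5.72 and Ace to -6.02 without control-diet mouse 2.

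**Figure D1:**
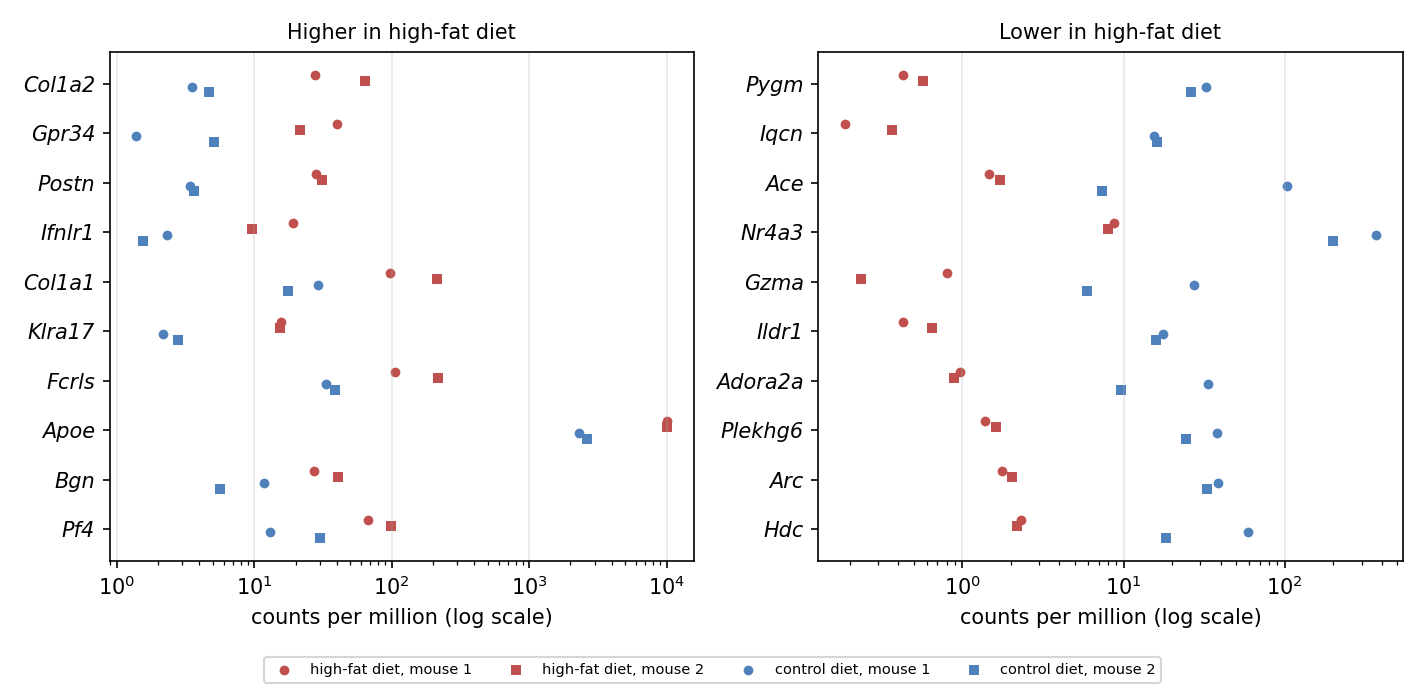
Each point is the CPM of 1 library (log axis) for the 10 leading genes in each direction, in red for high-fat diet and blue for control diet, with circles for mouse 1 and squares for mouse 2. Apoe had 10054 ± 55.8 CPM in the high-fat-diet and 2455 ± 232 CPM in the control-diet mice, and the control-diet mice lay apart from each other for Ace, at 104 and 7.31 CPM.

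Genes often measured in macrophages of obese hosts or tumours went in both directions. Mrc1, the mannose receptor, rose from 92.2 ± 15.1 to 161 ± 10.6 CPM (log2 fold change 0.80, SE 0.17, adjusted p = 0.0395). Cd274, which encodes the checkpoint ligand PD-L1, fell from 373 ± 101 to 165 ± 13.8 CPM (log2 fold change -1.17, SE 0.22, adjusted p = 0.0313), and Cd36, a fatty acid translocase, fell from 45.7 ± 22.1 to 16 ± 0.93 CPM (adjusted p = 0.0414). All of these calls ended without either high-fat-diet mouse, with adjusted p between 0.0955 and 0.259. The others were not called. Arg1 had 424 ± 123 against 886 ± 700 CPM (adjusted p = 0.244), Nos2 90.6 ± 30.7 against 190 ± 86 CPM (adjusted p = 0.111), Il1b 485 ± 11.8 against 958 ± 565 CPM (adjusted p = 0.152) and Tnf 97.5 ± 4.43 against 139 ± 2.57 CPM (adjusted p = 0.0665). Trem2 had 236 ± 18.6 against 179 ± 53.7 CPM (adjusted p = 0.28) and Spp1 264 ± 9.03 against 224 ± 17.1 CPM (adjusted p = 0.322). Pdcd1, which encodes PD-1, had 3.05 ± 0.332 against 2.55 ± 0.836 CPM (adjusted p = 0.624). The log2 fold change of Cd36 moved to -0.91 without control-diet mouse 2. Among the genes not called, fits without 1 library gave log2 fold changes from -1.7 to 0.12 for Arg1 and -1.48 to -0.2 for Il1b. Nos2 ran from -1.47 to -0.5, Tnf from -0.54 to -0.44, Trem2 from 0.13 to 0.74, Spp1 from 0.16 to 0.32 and Pdcd1 from -0.04 to 0.64.

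Genes of lipid-associated macrophages were higher in the high-fat-diet libraries as a list. Of 19 tested members 5 rose, Apoe, Gpnmb, Fabp4 and Cd63 among them, and 1 fell, Cd36, with 7 and 1 when adjusted over the list alone. By camera the adjusted p was 0.00791 (adjusted p = 0.885 with an estimated correlation). Gpnmb rose 2.11-fold to 37.4 ± 1.07 CPM and the fatty acid binding protein gene Fabp4 rose 3.61-fold to 3.39 ± 0.264 CPM. Cd63 rose 2.07-fold, and its count is uncertain because the pseudogene Cd63-ps, chosen after its values were seen, held more reads, 263 and 289 CPM in the high-fat-diet and 125 and 110 CPM in the control-diet libraries. Among 13 targets of the liver X receptors and genes of cholesterol efflux, Apoe rose and Mylip, an E3 ligase for the LDL receptor, fell 1.9-fold (1 and 1, or 2 and 1 when adjusted over the list alone, camera adjusted p = 0.711). Of 24 genes of PPAR targets and fatty acid oxidation, edgeR called 0, also when adjusted over the list alone (camera adjusted p = 0.424), and the smallest p was that of Hadh with 41.2 ± 1.84 against 29.4 ± 2.81 CPM. Of 24 genes of cholesterol biosynthesis, Insig1 fell 2.18-fold and Srebf2 fell 1.61-fold, also when adjusted over the list alone (camera adjusted p = 0.345). The camera direction of that list, lower with all libraries, turned to higher without high-fat-diet mouse 2. Without high-fat-diet mouse 1 the list passed camera's threshold as lower. Of 20 genes of fatty acid synthesis and desaturation, the desaturase gene Scd1 rose 1.73-fold and Dgat1, which makes triglycerides, fell 3.87-fold, also when adjusted over the list alone (camera adjusted p = 0.825). Dgat1 lies 0.102 kb past the 3' end of Hsf1. Of the calls named here, all but those of Apoe, Cd63 and Insig1 ended without high-fat-diet mouse 1 (adjusted p from 0.073 to 0.259), and all but those of Apoe without high-fat-diet mouse 2 (adjusted p from 0.0811 to 0.248). Srebf2 also lost its call without control-diet mouse 1 (adjusted p = 0.0579).

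Hypoxia and cell cycle genes were higher in the high-fat-diet libraries, as were mitochondrially encoded transcripts (median 1.27, camera adjusted p = 0.0168) and fibroblast and pericyte markers (median 1.47, 2e-07), each at adjusted p = 0.885 with an estimated correlation. Of 21 tested hypoxia genes 5 rose and 0 fell, 6 and 0 when adjusted over the list alone. Bnip3 rose 2.75-fold to 49.3 ± 1.09 CPM, Ak4 1.81-fold to 44.4 ± 1.23 CPM, Ero1l 1.91-fold and Bnip3l 1.67-fold. Over the whole list the camera adjusted p was 0.00791 (adjusted p = 0.885 with an estimated correlation), and 0.313 without high-fat-diet mouse 2. Of 36 tested cell cycle genes 35 had a positive log2 fold change, 8 rose and 0 fell, 15 and 0 when adjusted over the list alone. The list had a median of 0.67, a median log2 ratio of control-diet mouse 2 over mouse 1 of 0.57, and a camera adjusted p of 3.9e-09 (adjusted p = 0.885 with an estimated correlation). Ccnb1, which encodes cyclin B1, rose 3.3-fold to 23.9 ± 5.95 CPM, Ube2c rose 2.15-fold, Cdk1 1.76-fold and Tk1 1.59-fold. Glycolysis genes were not called as a list (20 tested, camera adjusted p = 0.214). Their camera direction, lower with all libraries, turned to higher without high-fat-diet mouse 1. Without high-fat-diet mouse 2 the glycolysis list passed camera's threshold as lower. The hexokinase gene Hk3 fell 2.26-fold and the phosphofructokinase gene Pfkp fell 2.56-fold, also when adjusted over the list alone, while Pgam1 had 108 ± 9.14 against 76.4 ± 1.98 CPM (adjusted p = 0.0747). Of 52 nuclear genes of oxidative phosphorylation, Uqcrb alone rose, 1.63-fold, and 0 were called when adjusted over the list alone (camera adjusted p = 0.188). That list was higher without high-fat-diet mouse 1 (0.00891) and without control-diet mouse 1 (0.00362). Among these calls of single genes, all but those of Bnip3 and Ero1l ended without high-fat-diet mouse 1 (adjusted p from 0.092 to 0.303), and all but those of Bnip3, Ccnb1 and Pfkp without high-fat-diet mouse 2 (adjusted p from 0.0817 to 0.166). Further calls lost were those of Ero1l, Bnip3l and Uqcrb without control-diet mouse 1 (adjusted p from 0.0587 to 0.0643).

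Inflammatory and interferon-gamma genes were lower in the high-fat-diet libraries. Of 27 inflammatory cytokines and NF-kB targets 3 fell and 1 rose, 12 and 2 when adjusted over the list alone. By camera the adjusted p was 0.00516 (adjusted p = 0.885 with an estimated correlation). Nlrp3, an inflammasome sensor, fell 3.46-fold from 430 ± 48.6 to 124 ± 10.9 CPM (log2 fold change -1.79, SE 0.17, adjusted p = 0.00808), Icam1 fell 2.34-fold, and Il23a, which lies 3.29 kb past the 3' end of Stat2, fell 16.5-fold from 1.36 ± 0.131 CPM. The neutrophil chemoattractant gene Cxcl1 rose 1.75-fold. Of 25 genes of the interferon-gamma response and T-cell chemokines 3 fell and 0 rose, 6 and 0 when adjusted over the list alone. Socs1 fell 5.07-fold, Irf1 2.66-fold from 787 ± 195 to 296 ± 58.8 CPM and Batf2 2.57-fold. Over the whole list the camera adjusted p was 0.00791 (adjusted p = 0.885 with an estimated correlation), 0.504 without high-fat-diet mouse 2 and 0.221 without control-diet mouse 1. Of 16 genes of MHC class II presentation the costimulatory ligand genes Cd80 and Cd86 fell, 3.24-fold and 1.92-fold, and 4 fell when adjusted over the list alone. By camera the adjusted p was 0.0212 (adjusted p = 0.885 with an estimated correlation), 0.129 without high-fat-diet mouse 2 and 0.286 without control-diet mouse 1. Of 22 genes of MHC class I presentation edgeR called 0, also when adjusted over the list alone (camera adjusted p = 0.353), and Tap2 had 152 ± 2.83 against 235 ± 47.8 CPM (adjusted p = 0.0786). Of 35 interferon-stimulated genes Ifit3b alone rose, 2.91-fold, and 0 were called when adjusted over the list alone (camera adjusted p = 0.269), while Oasl1 had 63.8 ± 8.26 against 117 ± 33 CPM (adjusted p = 0.0593). Lower too were the lists of neutrophil markers (median -3.61, camera adjusted p = 6.22e-06), dendritic cell markers (median -1.33, 0.0213) and immediate early genes (median -0.45, 0.0369), each at adjusted p = 0.885 with an estimated correlation. The median log2 ratio of control-diet mouse 2 over mouse 1 was -0.51 in the inflammatory, -0.48 in the interferon-gamma and -0.39 in the MHC class II list. The camera direction of the interferon-stimulated list, higher with all libraries, turned to lower without high-fat-diet mouse 1. That of the MHC class I list, lower with all libraries, turned to higher without high-fat-diet mouse 2 and without control-diet mouse 1. Yet the interferon-stimulated list passed camera's threshold as higher without high-fat-diet mouse 2, and the MHC class I list as lower without high-fat-diet mouse 1. Of the calls named here, all but those of Nlrp3 and Irf1 ended without high-fat-diet mouse 1 (adjusted p from 0.076 to 0.217), and all but those of Nlrp3 and Ifit3b without high-fat-diet mouse 2 (adjusted p from 0.0535 to 0.191). Ifit3b also lost its call without control-diet mouse 1 (adjusted p = 0.0545) and without control-diet mouse 2 (adjusted p = 0.0989). Some folds moved by over 1.5 times, on the log2 scale Ifit3b to 0.94 without high-fat-diet mouse 1, and Socs1 to -1.74 without control-diet mouse 1.

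Alternative activation genes split. Of 27 tested members 5 rose and 3 fell, 7 and 11 when adjusted over the list alone. The camera adjusted p was 0.967. The genes that rose were Pf4, Mrc1, the chemokine gene Ccl8 (3.45-fold), Selenop (2.56-fold, to 422 ± 44.7 CPM) and Lyve1, a marker of tissue-resident macrophages, with 69 counts in the high-fat-diet and 2 in the control-diet libraries, 31.7-fold (95% interval 8.45 to 267). Klf4, 2.78-fold lower, was among those that fell. The list's camera direction, lower with all libraries, turned to higher without high-fat-diet mouse 1 and without control-diet mouse 1. Without control-diet mouse 2 the list passed camera's threshold as lower. Of 21 immune checkpoints and suppressive ligands Cd274 fell and Cd276, which encodes B7-H3, rose 2.33-fold (adjusted p = 0.0498), 1 and 0 when adjusted over the list alone. The camera adjusted p was 0.287. Pdcd1lg2 had 3.1 and 3.57 CPM in the high-fat-diet mice, 58.1 CPM in control-diet mouse 1 and 7.15 CPM in control-diet mouse 2 (adjusted p = 0.0685). Of 27 genes of angiogenesis and matrix remodelling 6 rose and 1 fell, 7 and 4 when adjusted over the list alone (camera adjusted p = 0.188). The camera direction of that list, higher with all libraries, turned to lower without control-diet mouse 2. Without high-fat-diet mouse 1 and without control-diet mouse 1 the list passed camera's threshold as higher. Of 19 fibroblast and pericyte markers 9 rose, 16 were higher and 1 lower when adjusted over the list alone, and the median was 1.47 (camera adjusted p = 2e-07, adjusted p = 0.885 with an estimated correlation). Tnc, which encodes tenascin C, rose 14.4-fold, Pdgfc 2.8-fold and Mmp2 2.16-fold, and Thbs1, which encodes thrombospondin 1, fell 5.23-fold from 1499 ± 1004 CPM. Among these calls of single genes, all but those of Ccl8 and Lyve1 ended without high-fat-diet mouse 1 (adjusted p from 0.0714 to 0.336), and all but those of Cd276 and Pdgfc without high-fat-diet mouse 2 (adjusted p from 0.06 to 0.224). Cd276 also lost its call without control-diet mouse 1 (adjusted p = 0.0745) and without control-diet mouse 2 (adjusted p = 0.0688). Leaving out 1 library moved some folds by over 1.5 times, on the log2 scale Tnc to 3.23 and Thbs1 to -1.45 without control-diet mouse 1, and Tnc to 5.08 without control-diet mouse 2. Fitted log2 fold changes of Lyve1, which depend on the prior count, ran from 4.08 to 5.33 in these fits, the lowest without high-fat-diet mouse 2.

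Genes of recently arrived monocytes were lower in the high-fat-diet libraries, and within the control diet most were higher in mouse 1. Of 18 tested members Thbs1 and Ifitm6 fell, 9 fell when adjusted over the list alone. The camera adjusted p was 0.0344 (adjusted p = 0.885 with an estimated correlation), and 0.348 without control-diet mouse 1. The median log2 ratio of control-diet mouse 2 over control-diet mouse 1 across the list was -1.45. Lower too were the lists of neutrophil markers (median -3.61), dendritic cell markers (median -1.33, log2 ratio of mouse 2 over mouse 1 -1.42) and immediate early genes (median -0.45), with camera adjusted p of 6.22e-06, 0.0213 and 0.0369, each at adjusted p = 0.885 with an estimated correlation. Of 22 genes of the unfolded protein response Ppp1r15a fell 2.31-fold, Hyou1 1.8-fold and Dnajb9 1.7-fold, 6 fell when adjusted over the list alone. The camera adjusted p was 0.0491 (adjusted p = 0.885 with an estimated correlation), 0.126 without high-fat-diet mouse 1 and 0.597 without control-diet mouse 1. In the list of insulin, leptin and adipokine signalling, with 17 tested, the insulin receptor substrate gene Irs2 fell 2.56-fold, Stat3 1.82-fold and Il6ra 1.61-fold among 4 that fell, and Igf1 rose 3.31-fold, with 4 and 1 also when adjusted over the list alone (camera adjusted p = 0.131, and 0.0493 without control-diet mouse 2, lower). Of 35 lysosome genes Gla fell 2.14-fold (0 when adjusted over the list alone, camera adjusted p = 0.364), and of 20 genes of iron and heme handling Txnrd1 fell 1.9-fold (0 when adjusted over the list alone, camera adjusted p = 0.567). Of the calls named here, all ended without high-fat-diet mouse 1 (adjusted p from 0.0966 to 0.488), and all but those of Irs2 and Gla without high-fat-diet mouse 2 (adjusted p from 0.0636 to 0.354). Also lost were those of Hyou1, Stat3 and Il6ra without control-diet mouse 1 (adjusted p from 0.0568 to 0.0687).

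**Figure D2:**
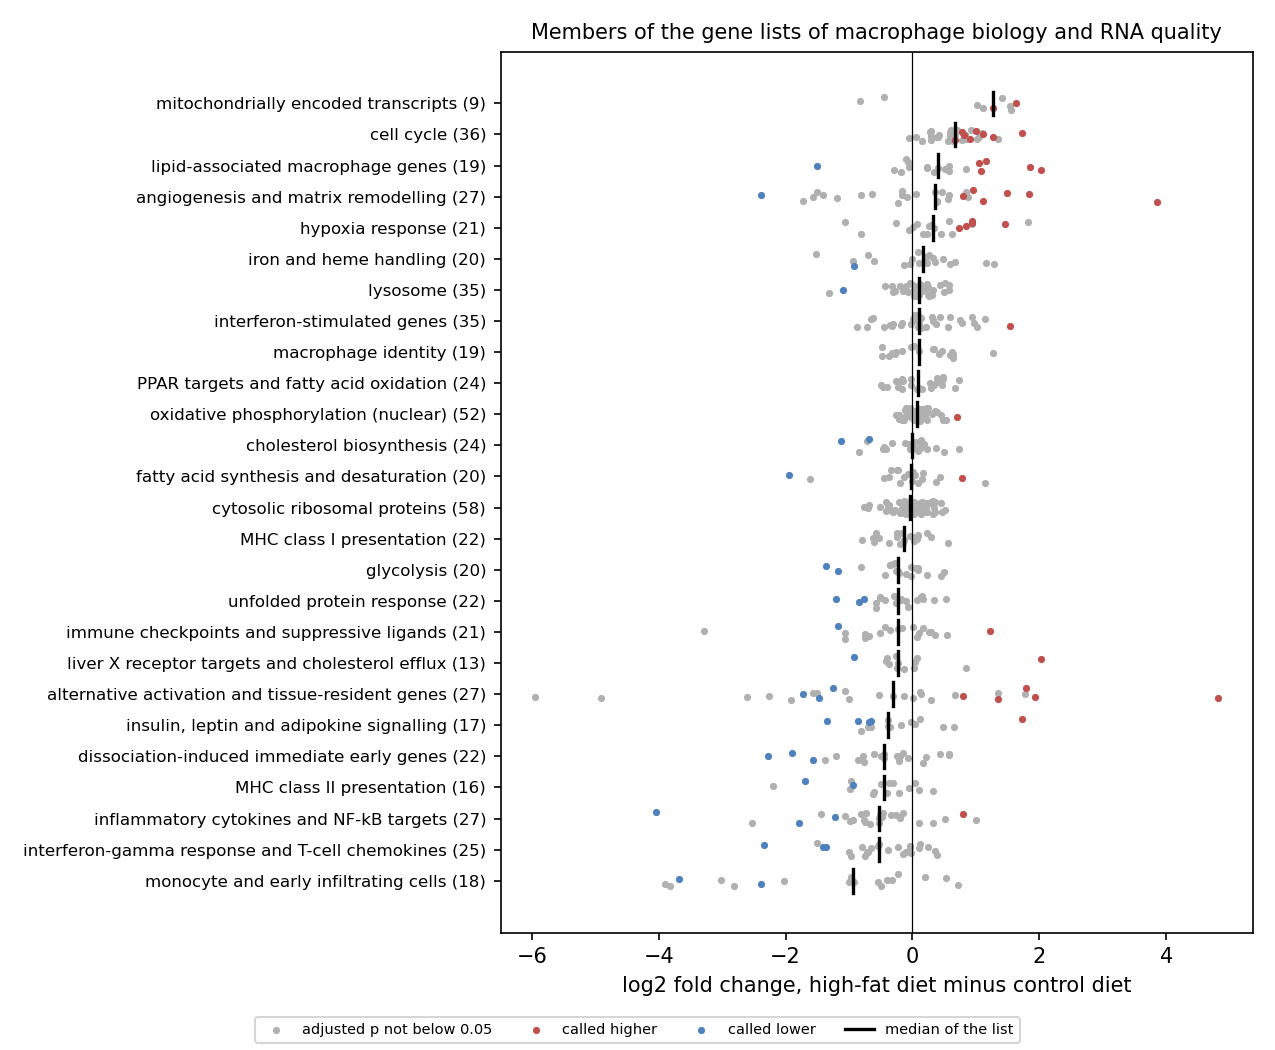
Each point is the log2 fold change of 1 gene, high-fat diet minus control diet, in the lists of macrophage biology and RNA quality, with the number of tested members in parentheses, red for called higher, blue for called lower and grey for not called, and a bar at the list's median. The median of the cell cycle list was 0.67 and that of the monocyte list -0.94.

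Lists that follow RNA quality and handling moved too. Of 9 tested mitochondrially encoded transcripts mt-Nd1 rose 3.12-fold and mt-Co1 2.41-fold, 7 rose when adjusted over the list alone. The camera adjusted p was 0.0168 (adjusted p = 0.885 with an estimated correlation), and 0.135 without control-diet mouse 1. Mitochondrial transcripts held 2.67 and 1.59% of the counts of the high-fat-diet libraries and 0.757 and 1.2% of those of the control-diet libraries. Of 22 immediate early genes known to respond to tissue dissociation 3 fell, Egr3 4.85-fold, Nr4a1 3.72-fold from 988 ± 530 to 266 ± 10 CPM and Ier3 2.98-fold, and 5 fell when adjusted over the list alone. Their camera adjusted p was 0.0369 (adjusted p = 0.885 with an estimated correlation), 0.0651 without high-fat-diet mouse 1 and 0.348 without control-diet mouse 1. The median log2 ratio of control-diet mouse 2 over mouse 1 was 0.57 in the mitochondrial and -0.49 in the immediate early list. Of 58 cytosolic ribosomal protein genes edgeR called 0, also when adjusted over the list alone (camera adjusted p = 0.962), and their low levels, such as 11.3 ± 2.02 against 19.3 ± 0.339 CPM for Rpl28, are uncertain because processed pseudogenes share their sequence. Among these calls of single genes, all ended without high-fat-diet mouse 1 (adjusted p from 0.0873 to 0.235), and all but those of mt-Nd1 and Ier3 without high-fat-diet mouse 2 (adjusted p from 0.0576 to 0.192). Further calls lost were those of mt-Nd1 and mt-Co1 without control-diet mouse 1 (adjusted p from 0.0569 to 0.0922). Some folds moved by over 1.5 times, on the log2 scale mt-Nd1 to 1.02 without high-fat-diet mouse 1, and Nr4a1 to -1.20 without control-diet mouse 1.

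Markers of other cell types differed between the diets in both directions. Of 16 tested tumour epithelial markers 12 fell and 0 rose in the high-fat-diet libraries, with a median log2 fold change of -4.03, also with the genes at 0 set to their bound. Here 13 fell and 1 rose when adjusted over the list alone (camera adjusted p = 8.38e-05, adjusted p = 0.885 with an estimated correlation). The keratin gene Krt19 fell from 7.65 ± 6.98 to 0.0658 ± 0.0175 CPM, Krt18 fell from 4.99 ± 4.05 to 0.0524 ± 0.0364 CPM, and Vil1 fell 22.7-fold. The claudin gene Cldn4 had 1 count in the high-fat-diet and 184 in the control-diet libraries, a ratio of 200 (95% interval 35.5 to 7955). Of 15 neutrophil markers 10 fell and 0 rose, 12 and 0 when adjusted over the list alone, with a median of -3.61 (camera adjusted p = 6.22e-06, adjusted p = 0.885 with an estimated correlation). S100a9 fell 16.2-fold from 40.1 ± 21.6 CPM, S100a8 fell 10.6-fold, Lcn2 fell 27.3-fold and Mpo had 2 against 79 counts, a ratio of 43 (95% interval 11.5 to 361). Of the low-count genes here, Lcn2 lies 3.66 kb past the 3' end of Ciz1 and Txk 2.94 kb past that of Tec. Vil1 overlaps the expressed gene Usp37, which lies on the opposite strand. Of 17 dendritic cell markers Clec9a fell 5.68-fold, Wdfy4 2.16-fold and Cd209a 35.9-fold (11.3 CPM in control-diet mouse 1), and 5 fell when adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.885 with an estimated correlation, 0.229 without control-diet mouse 1). Of 9 markers of eosinophils, mast cells and basophils Tpsb2 fell 8.66-fold and Cma1 7.48-fold, and 5 fell when adjusted over the list alone (camera adjusted p = 0.0344, adjusted p = 0.885 with an estimated correlation, 0.348 without control-diet mouse 1). The median log2 ratio of control-diet mouse 2 over mouse 1 was 1.4 in the epithelial, -0.95 in the neutrophil, -1.42 in the dendritic cell and -1.39 in the eosinophil, mast cell and basophil list. Natural killer and cytotoxic markers (17 tested, camera adjusted p = 0.131) had Gzma and Txk lower and Klra4 higher, 3 and 2 when adjusted over the list alone. That list was lower without high-fat-diet mouse 1 (0.0492) and without control-diet mouse 2 (1.34e-05). Of the calls named here, all but those of Vil1, Cldn4, S100a8, Lcn2, Clec9a and Tpsb2 ended without high-fat-diet mouse 1 (adjusted p from 0.0732 to 0.476), and all but those of Vil1, Cldn4, S100a8, Lcn2 and Clec9a without high-fat-diet mouse 2 (adjusted p from 0.0633 to 0.371). Leaving out 1 library moved some folds by over 1.5 times, on the log2 scale Cma1 to -3.69 without high-fat-diet mouse 1, and Krt18 to -7.35 without high-fat-diet mouse 2. Further moves were Krt19 to -7.50, Krt18 to -7.12, S100a9 to -3.32 and Cd209a to -2.82 without control-diet mouse 1, and Krt19 to -5.29, Krt18 to -5.24 and Cd209a to -6.02 without control-diet mouse 2. Fitted log2 fold changes that depend on the prior count ran from -9.51, without high-fat-diet mouse 2, to -6.38, without control-diet mouse 2, for Cldn4, which was also at -6.43 without high-fat-diet mouse 1, and to -4.61, without control-diet mouse 1, for Mpo.

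Fibroblast and pericyte markers went the other way. Of 19 tested 9 rose and 0 fell, 16 and 1 when adjusted over the list alone, with a median log2 fold change of 1.47 (camera adjusted p = 2e-07, adjusted p = 0.885 with an estimated correlation). Besides Col1a2 and Postn, Col5a2 rose 2.85-fold from 22.8 ± 1.53 to 65.1 ± 0.415 CPM and the pericyte gene Rgs5 rose 23.2-fold from 0.52 ± 0.355 CPM. T cell markers (22 tested) had 1 gene higher, Cd4, 7.64-fold, also when adjusted over the list alone. Its camera adjusted p was 0.0493 (adjusted p = 0.885 with an estimated correlation), 0.0726 without high-fat-diet mouse 2 and 0.927, in the opposite direction, without control-diet mouse 2, and the median log2 ratio of control-diet mouse 2 over mouse 1 was -0.83. Of 9 B and plasma cell markers Igkc fell 82.8-fold and Cd79a 34.7-fold, also when adjusted over the list alone. The median of the list was 0.23, its mean -1.03 and its camera adjusted p 0.87. Of 12 endothelial markers Eng fell 1.65-fold, and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.512). Of 8 skeletal muscle and keratinocyte markers Tnnt3, 3.97 kb past the 3' end of Lsp1, fell 7.1-fold and Acta1 7.31-fold, and 3 fell when adjusted over the list alone (camera adjusted p = 0.428). Of 5 erythroid markers edgeR called 0, also when adjusted over the list alone (camera adjusted p = 0.428). The camera direction of that list, higher with all libraries, turned to lower without high-fat-diet mouse 1. Without high-fat-diet mouse 2 the list passed camera's threshold as higher. Of the adipocyte markers 3 were tested, too few for camera. Fabp4 rose, Lipe fell 1.62-fold, and Pck1, with 0 counts in the high-fat-diet libraries, was at least 17.4-fold lower, also when adjusted over the list alone. Among these calls of single genes, those of Eng, Tnnt3, Acta1, Fabp4, Lipe and Pck1 ended without high-fat-diet mouse 1 (adjusted p from 0.118 to 0.228), and the same 6 without high-fat-diet mouse 2 (adjusted p from 0.0927 to 0.217). Lipe also lost its call without control-diet mouse 1 (adjusted p = 0.0581), and Acta1 without control-diet mouse 2 (adjusted p = 0.0682). Pck1 was not tested without control-diet mouse 1. Some folds moved by over 1.5 times, on the log2 scale Cd79a to -5.99 without high-fat-diet mouse 2, and Rgs5 to 5.46 without control-diet mouse 1. Likewise, Rgs5 moved to 3.95, Igkc to -5.57 and Acta1 to -2.20 without control-diet mouse 2.

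**Figure D3:**
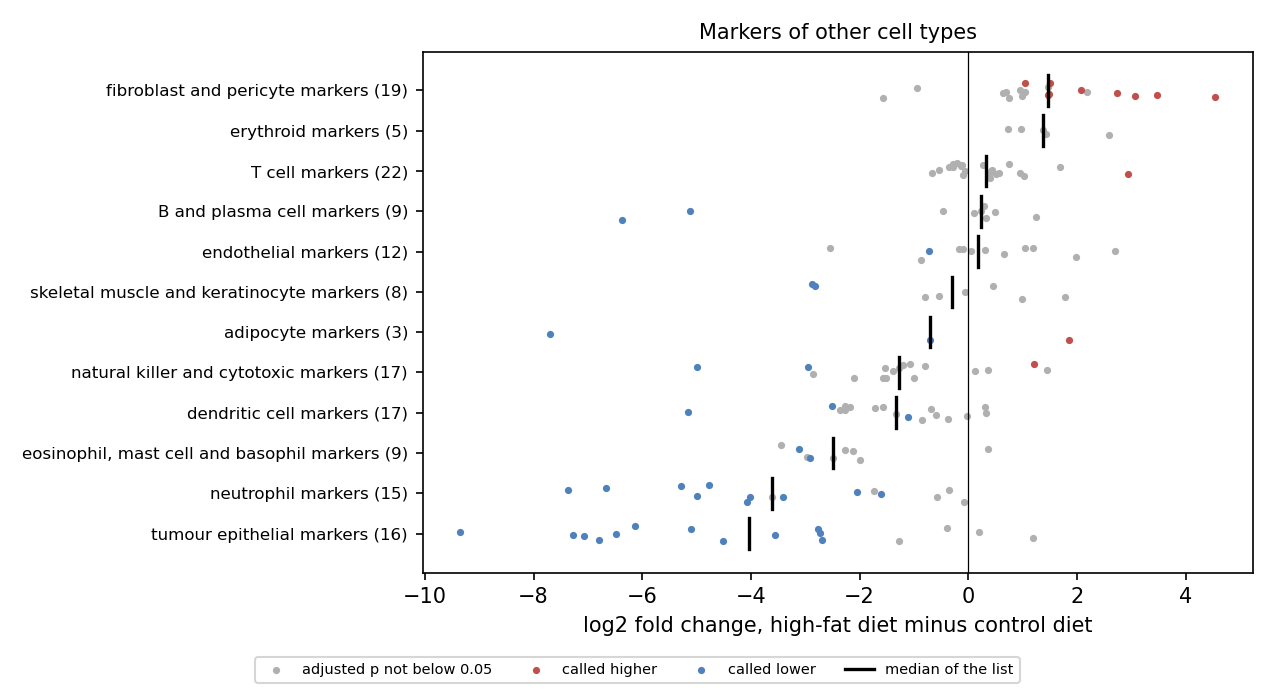
Each point is the log2 fold change of 1 marker, high-fat diet minus control diet, with the number of tested markers in parentheses, red for called higher, blue for called lower and grey for not called, and a bar at the list's median. Medians ran from -4.03 for the tumour epithelial markers to 1.47 for the fibroblast and pericyte markers.

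Low-count genes next to expressed genes differed by position. Within 10 kb past the 3' end of an expressed gene, 790 low-count genes had a median log2 fold change of -1.37 (95% interval -1.56 to -1.18), and 288 of them (36.5%) were called lower. Within 10 kb before the 5' start, 551 genes had a median of -0.17 (-0.27 to -0.06), and 1850 genes with no expressed gene within 100 kb had a median of 0.26 (0.2 to 0.3). The median past gene ends was -1.44 for genes on the same strand as the expressed gene and -1.29 for genes on the opposite strand, and at 30 to 100 kb it was -0.05. Low-count genes that overlap an expressed gene had a median of -0.73 on the same strand (555 genes, 55 lower and 0 higher) and -0.56 on the opposite strand (916 genes, 131 lower and 10 higher). Summed over the genes past gene ends, the libraries held 650 and 673 CPM in the high-fat-diet mice and 1310 and 1274 CPM in the control-diet mice. Log2 fold changes also followed GC content: over 9318 protein-coding genes with an average log2 CPM of at least 3, Spearman's rho with transcript GC content was -0.321 and with transcript length -0.0977, across genes, which are not independent replicates.

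**Figure D4:**
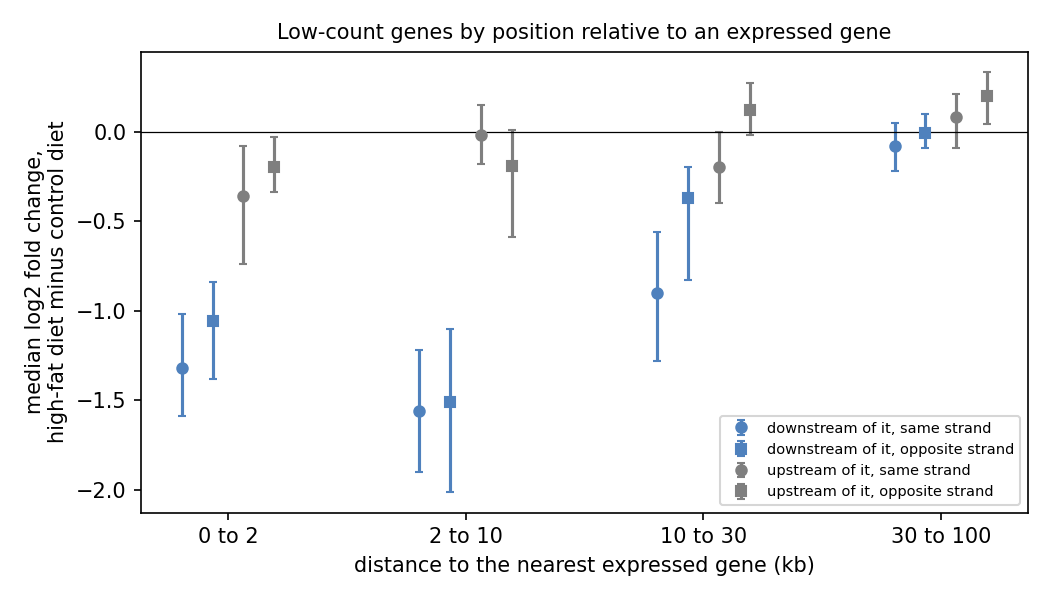
Points are medians of the log2 fold change, high-fat diet minus control diet, of low-count genes by distance in kb to the nearest expressed gene, blue for genes past its 3' end and grey for genes before its 5' start, circles for the same and squares for the opposite strand, with bootstrap 95% intervals. Past gene ends the medians lay at -1.56 and -1.51 between 2 and 10 kb and at -0.08 and -0.01 between 30 and 100 kb.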

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

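The fit was repeated under alternatives fixed before the data were examined. The correction for GC content and length, the fits without genes near gene ends or overlapping expressed genes and the crossed pairing were chosen after seeing the data. All 1937 calls kept their direction with DESeq2 size factors, library size alone, the DESeq2 Wald test, limma-voom, no filter, no robust estimation, the replicate block and the GC and length correction. These fits reuse the same libraries, and in all 1937 genes the libraries of the diets did not overlap. A change of direction was therefore hardly possible, and the kept direction is no test of the calls. Counts of higher and lower genes stayed within 1.5 times under DESeq2 size factors, library size alone, limma-voom, no robust estimation, the replicate block, and the GC and length correction with and without that block. The DESeq2 Wald test called 1082 genes higher. Without a filter 1552 were higher and 2231 lower, so that 59% of the calls were lower against 75.2%, and a filter of at least 1 CPM in 2 libraries gave 305 higher. A log2 fold change of at least 1 left 312 higher, and an adjusted p below 0.10 gave 1476 higher and 2463 lower. Without genes within 30 kb past the 3' end of an expressed gene 14508 genes were tested, and 234 were higher and 665 lower. Without genes that overlap an expressed gene as well, 11972 were tested, and 35 were higher and 135 lower. Of the 1009 called genes still tested, 170 stayed called. That fit left their counts and scaling unchanged, so their direction was fixed beforehand. In fits without 1 library, counts ranged from 71 to 1934 higher and from 300 to 2534 lower genes; these fits leave 1 mouse in a diet, which is assumed to vary like the other diet's mice. Whether the wider spread of the control-diet pair alone accounts for these differences was not tested. Library size alone moved the median of all genes by 0.069 on the log2 scale, the most of the scalings tried.

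Of 101 called genes named by the rule, 32 stayed called without high-fat-diet mouse 1, 34 without high-fat-diet mouse 2 and 97 without control-diet mouse 2, and of 100 tested 88 without control-diet mouse 1. Calls stayed for 88 with limma-voom, 85 without a filter and 87 with the GC and length correction, for 84 of 97 tested with at least 1 CPM in 2 libraries, and for 59 of 74 without genes past gene ends. The block on replicate number, a number that names different animals in each diet, kept 92 of the 101 calls and gave 567 higher and 1481 lower genes. Deviations of mice with the same number correlated at -0.119, and the crossed pairing gave 909 higher and 1546 lower genes.

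Camera called 6 lists higher and 10 lower. With an estimated correlation and with fry's directional p it was 0 higher and 0 lower at adjusted p. With the estimated correlation 0 lists had an unadjusted p below 0.05, and fry's mixed p passed for 13 lists. Camera with an estimated correlation rests on 2 residual degrees of freedom, so its nulls do not decide the lists. The lipid-associated list had an estimated correlation of -0.0202, below the preset, yet its camera p rose from 0.00153 to 0.075. The cell cycle list had 0.882, far above the preset, and a camera p of 0.315. Both have the same adjusted p of 0.885. Without 1 library camera called 5 to 8 lists higher and 3 to 13 lower, the 3 without control-diet mouse 1. The T cell list turned to lower without control-diet mouse 2 (adjusted p = 0.927) and was higher without control-diet mouse 1 (adjusted p = 4.41e-05). In simulated data 52% of genes changed by a log2 fold of 1, all with an average log2 CPM of at least 1, were recovered.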

Other observations

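The called genes of this part were chosen after their values were seen, belong to no list fixed beforehand, and stand as single genes, not as a tested group. Cx3cr1, Csf1r, Fos and Egr1, list members that were not called, were also named after their values were seen. Tmem119, a gene expressed by microglia, rose 2.39-fold to 349 ± 24.3 CPM (SD, n = 2, edgeR adjusted p = 0.0235, and 0.0668 without high-fat-diet mouse 2). The purinergic receptor genes P2ry12 and P2ry13 rose 2.79-fold and 2.07-fold (adjusted p = 0.0365 and 0.0339, both 0.158 without high-fat-diet mouse 1, and P2ry12 0.0596 without high-fat-diet mouse 2), while the list members Cx3cr1 and Csf1r, also expressed by microglia, were not called (log2 fold change 0.46 and -0.32). The transcription factor gene Maf rose 2.25-fold from 156 ± 51.8 to 351 ± 3.06 CPM (adjusted p = 0.0375), and Rgs1, a regulator of G-protein signalling, rose 3.19-fold to 1520 ± 36.8 CPM (adjusted p = 0.0438). Both calls ended without high-fat-diet mouse 1 (0.129 for Maf, 0.245 for Rgs1) and without high-fat-diet mouse 2 (0.117 and 0.181). The non-coding RNA H19 rose 2.72-fold to 460 ± 19.6 CPM (adjusted p = 0.0163) and the transcription factor genes Prrx1 and Twist1 rose 3.19-fold and 1.83-fold, beside fibroblast and pericyte markers with 9 of 19 called higher and a median log2 fold change of 1.47 (adjusted p = 0.885 with an estimated correlation). Twist1 lost its call without high-fat-diet mouse 1 (0.245) and without high-fat-diet mouse 2 (0.154).

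Among genes that fell, Nr4a2 fell 14.2-fold from 588 ± 205 to 41.5 ± 2.02 CPM (SD, n = 2, adjusted p = 0.00557) and Crem, a regulator of cyclic AMP-dependent transcription, fell 7.57-fold from 72.7 ± 15.3 to 9.6 ± 1.49 CPM (adjusted p = 0.00557). The phosphodiesterase genes Pde4b and Pde4d fell 5.35-fold and 3.06-fold, and Sik1 fell 2.69-fold (adjusted p = 0.0139), with Pde4d at 0.124 and Sik1 at 0.0568 without high-fat-diet mouse 1. Of the 22 immediate early genes tested as a list, 17 were negative and 3 fell, Nr4a1, Egr3 and Ier3, while Fos and Egr1, with log2 fold changes of 0.58 and -0.49, were not called (camera adjusted p = 0.0369, lower, adjusted p = 0.885 with an estimated correlation). Hcar2, a receptor for ketone bodies and niacin, fell 4.09-fold from 127 ± 50.7 CPM (adjusted p = 0.0176, and 0.111 and 0.0761 without high-fat-diet mouse 1 and without high-fat-diet mouse 2). Hexim1, an inhibitor of the elongation factor P-TEFb, fell 3.79-fold from 248 ± 7.92 CPM, and Rn7sk, the RNA in the same complex, fell 3.48-fold from 95.1 ± 0.252 CPM (adjusted p = 0.00596 and 0.00615).

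In the patterns weighed here, the tests on isolated genes, the fit without overlapping genes and all tests on markers of other cell types were chosen after the result was seen, and the others before. A looser reading of the bounds, tried once these values had been seen, counted GC content and length out for the direction of the calls. It was dropped, and an explanation is counted out here only where the whole interval lies past the bound written for it. These intervals run over genes of the same libraries, which are not independent replicates, and do not measure the spread between mice. The first pattern is the excess of low-count genes past gene ends in the control-diet libraries. Genomic DNA would raise genes far from expressed ones there too, and their median was 0.26 (95% interval 0.2 to 0.3) in the other direction. After the correction for GC content and length the difference between genes past 3' ends and before 5' starts was -1.15 (-1.37 to -0.96), against -1.2 before it. This argues against the trend seen in genes with an average log2 CPM of at least 3, on which the correction was fitted, as the whole source. A trend with GC content or length particular to low-count genes would outlast the correction, so it stays open. Transcription running on past gene ends may be the source, but the excess followed the neighbour's level with rho 0.137 (0.0697 to 0.204), against 0.112 for genes before 5' starts, which does not decide it. Whether the diet, the tumours or the handling of the cells brought the excess was not tested.

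The second pattern is that most calls were lower. Without genes within 30 kb past an expressed gene 74% of 899 calls were lower (95% interval 71 to 76.8), which argues against transcription past gene ends as the whole source. Leaving out genes that overlap an expressed gene as well, a fit added last, 79.4% of 170 calls were lower (72.5 to 85.2). After the GC and length correction 71.7% of 2449 calls were lower (69.8 to 73.4). The interval crosses the bound of 70% written beforehand for counting the trend out, and lies above the 60% the trend would need, so a part for GC content and length stays open, as does the diet, untested.

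The third pattern is the markers of other cell types. A lower share of macrophages in the control-diet sorts, with more of every other type, would raise fibroblast and pericyte markers there too. Their median, 1.47 (95% interval 0.96 to 2.08), was higher in the high-fat-diet libraries. It does not speak to more of only some types in either diet's sorts, which was not tested. Transcription past gene ends was left open by the first test, the difference of epithelial markers and low-count genes past gene ends in the log2 ratio of control-diet mouse 2 over mouse 1, 1.37 (-0.05 to 1.96), and by a further test against a bound of 35%, with 19.4% of the 36 markers that fell within 30 kb past an expressed gene (8.19 to 36; 21.2% of all tested genes). A test added last cannot decide it, because it took the 4 lists called lower in these same data (adjusted p = 0.885 each with an estimated correlation). Of their 57 tested markers, 50 neither overlap an expressed gene nor lie within 30 kb past one. Those 50 had a median of -2.31 (-3.04 to -1.86), so the fall was not confined to markers near gene ends. Epithelial cells or their RNA in the control-diet sorts may account for the 12 of 16 epithelial markers that fell. The most abundant, Ly6a, named after its values were seen, had 547 CPM in the control-diet libraries and was not called. As 1 member it does not decide this. The CD45 gate is meant to remove such cells, but it does not settle the question either. The fibroblast and pericyte marker Col1a1 had 23.4 ± 8.21 CPM in the control-diet and 155 ± 81.4 CPM in the high-fat-diet libraries. A change of the macrophages with diet or engulfed tumour RNA was not tested.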
